A study of Homo sapiens with 10 samples.

How the data were processed

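The series measured RNA of TPC-1, an established human papillary thyroid carcinoma cell line that carries a RET/PTC1 fusion. Cells were transfected with an empty vector (EV) or with a vector for overexpression (OE) of PTCSC3-AS1, a long non-coding RNA named for its antisense position to PTCSC3. There were 5 EV and 5 OE libraries, numbered 1 to 5 in each group. Per the labels, total RNA was extracted with TRIzol, treated with DNase I and made into libraries with the NEBNext Ultra RNA kit, which were sequenced in paired ends on an Illumina NovaSeq instrument. Whether RNA was selected by its poly(A) tail is not given in the sources used here. The design text speaks of 5 pairs and does not say what joins a pair, and the main tests treat the libraries as unpaired. Replicates 1 to 3 of each group are in 1 deposited table, here called the first set, and replicates 4 and 5 in another, here called the second set. Per the file headers, the OE columns are named EST_OE in the first set and OE in the second set. Whether the vector was the same, and what else separates the sets (day, culture or sequencing run), is not given in the sources used here, and neither is whether replicates came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical in part.

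Per the submitters' processing notes, CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used with the genome build hg38. The role and order of these tools and the annotation release are not given in the sources used here. Per the file headers, each table deposited by the authors holds a raw count per gene and library, and the values are whole numbers. A gene length in bases stands beside the counts in the deposited tables. The authors' second table also gives, per the file headers, a log2 fold change, a p-value and an adjusted p-value for OE replicate 4 against EV replicate 4 and for OE replicate 5 against EV replicate 5. The 14 deposited per-library columns of FPKM or normalized values were not used. Both tables list 58735 genes, all of which have an identifier in GENCODE 29, and 58724 have identical start and end there. Gene symbols are those of the deposited tables.

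Counts of the tables were joined by gene identifier. The depth was 15761474 to 18066559 counts per library, so 3 counts, the floor used for a gene with a count of 0, equal 0.166 to 0.190 CPM (counts scaled by the size of the library). This floor covers counting error only. Counts of any 2 libraries of a group differed by more than sampling noise (chi-square per degree of freedom 4.30 to 53.1 over genes with at least 20 counts), so no library was a copy of another of its group. Principal components were taken on the 1000 most variable genes.

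The following choices were made before the data were examined. The comparison of OE with EV used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with a dispersion estimated first, TMM scaling, the default filterByExpr filter, the set as a term, and Benjamini-Hochberg adjusted p under 0.05. Each set was also fitted alone with its own dispersion, and an interaction term tested whether the change differed between the sets. Fold changes are OE over EV on the log2 scale, with the standard error (SE) implied by the test, and CPM values are scaled by TMM factors. Intervals are at the 95% level. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. A list needed 3 tested members.

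The 33 lists covered the neighbourhood of PTCSC3 on chromosome 14, thyroid differentiation, MAPK pathway output, RET and receptor tyrosine kinase signalling, interferon response, antigen presentation, and NF-kB and inflammatory cytokines. Others covered G1/S and DNA replication, G2/M and mitosis, p53 targets, apoptosis regulators, mesenchymal and epithelial genes, matrix proteases, the S100 family, and targets of TGF-beta, YAP/TAZ, Wnt, Notch and NRF2. The rest covered the unfolded protein and integrated stress response, heat shock, hypoxia and glycolysis, cholesterol synthesis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, replication-dependent histones, and small RNA processing. Markers of fibroblasts, leukocytes, endothelium and neuroendocrine cells stood for other cell types. Of 713 list members, 710 were matched to the tables. The leukocyte list had 1 tested member, so 32 lists were tested.

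The genes named in the text follow a fixed rule. It takes the tested genes of the PTCSC3 neighbourhood. From the fit over both sets it takes up to 12 of the largest rises and falls among genes past the threshold with log2 CPM of at least 1, a symbol, and the same sign in each set. From each set and the interaction it takes up to 5 per direction, and from each list the 4 members with the lowest p where the list was called and 2 otherwise. Genes named outside this rule are marked as chosen after their values were seen.

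Alternatives fixed at that time were DESeq2 size factors, upper-quartile scaling, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a mean CPM of at least 1, a fold change of at least 2, no set term, the replicate number as a block, a spread pooled over both sets, and leaving out each library in turn. Alternatives chosen after the data were seen were the edgeR version 4 form of the quasi-likelihood test, camera with a variance trend, and offsets that removed each library's trend on GC content and transcript length (natural splines with 4 degrees of freedom each). GC content and length came from the longest transcript of each gene in GENCODE 29, which gave a value for 99.96% of 14217 genes. The comparisons of the second set with the first set and of replicate 5 with replicate 4 were chosen after the data were seen as well.

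Each fit was tested on simulated data made from these libraries, in which known genes were given a changed level, in 5 simulations. At a 2-fold change, the fit over both sets called 81.5% of such genes, the first set alone 74.6%, the second set alone 64.8% and the interaction 49.0%. At a 1.5-fold change these shares were 64.8%, 34.3%, 27.8% and 8.66%. Of all calls in the simulations, 5.76% (both sets), 6.06% (first set), 8.47% (second set) and 5.43% (interaction) were of genes that had not been changed. Simulated counts were drawn for each gene on its own, without the differences shared across many genes that these libraries show. The shares in the real data may therefore differ from these. The authors' comparisons of single libraries were read as deposited and enter no comparison of the groups.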

Results

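RNA was sequenced from TPC-1 cells with an empty vector (EV, n = 5) or with PTCSC3-AS1 overexpression (OE, n = 5). The first set holds replicates 1 to 3 of each group and the second set replicates 4 and 5. The libraries held 15761474 to 18066559 counts, with 20630 to 22029 genes detected. Log2 CPM of libraries correlated across genes at r = 0.974 to 0.992 within a set and 0.968 to 0.983 between sets. The first principal component held 35.8% of the variance and set the first set (scores of -19.2 to -9.26) apart from the second set (scores above 0, up to 21.7). EV replicate 2 stood apart on the second component (14.4% of the variance), at -22.2 against -8.37 to 10.8 for the other libraries.

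The overexpressed transcript itself was not measured. PTCSC3-AS1 was not among the gene names of the tables. Its neighbour PTCSC3 (ENSG00000259104, hg38 chromosome 14, 36136108 to 36176468, minus strand) and the overlapping LINC00609 (ENSG00000257585, chromosome 14, 36070427 to 36165288, plus strand) had 0 counts in all 10 libraries. A count of 0 allows up to 0.166 to 0.190 CPM per library. The OE labels could therefore not be checked against the level of the transcript.

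Around the PTCSC3 locus, 8 of 17 listed genes were tested, and 0 rose or fell over all genes tested. BRMS1L, which encodes a subunit of a histone deacetylase complex, had a log2 change of -0.34 (SE 0.10, n = 5 per group) and was the 1 gene called lower when adjusted over the list alone. MBIP had -0.28 (SE 0.10), PAX9 -0.21 (SE 0.16), MIPOL1 -0.10 (SE 0.13), RALGAPA1 -0.10 (SE 0.15), FOXA1 -0.05 (SE 0.15), NFKBIA 0.07 (SE 0.09) and SLC25A21 0.32 (SE 0.28). As a list these neighbours had a median of -0.08 and were not called (camera, adjusted p = 0.0924). The signs for FOXA1 and RALGAPA1 turn when single libraries are left out.

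Over both sets, camera with the preset correlation called histone, mitochondrially encoded and p53 target RNA lower in OE cells as lists, and antigen presentation and epithelial RNA higher. None of these 5 calls held with an estimated correlation (adjusted p = 0.375 to 0.875). All 13 tested replication-dependent histone genes lay below 0, with a median log2 change of -0.40, which comes from the first set (-0.79, against -0.02 in the second set). HIST1H2BC changed by -1.13 (SE 0.31), HIST1H4H by -0.85 (SE 0.34), HIST1H2BD by -0.60 (SE 0.18) and HIST1H2AC by -0.51 (SE 0.17), all as estimates that did not pass the test over all genes. The 15 mitochondrially encoded genes all lay below 0 as well, with a median of -0.13. The ribosomal RNAs MT-RNR1 and MT-RNR2 had -0.47 (SE 0.15) and -0.24 (SE 0.09), and MT-ND1 and MT-ND2, subunits of respiratory complex I, -0.17 (SE 0.06) each. For the ribosomal RNAs this comes mostly from the first set (-0.77 and -0.33, against -0.03 and -0.11 in the second set), while MT-ND1 and MT-ND2 had -0.18 and -0.16 in the first set and -0.16 and -0.19 in the second set.

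Targets of p53 had a median of -0.08, with 17 of 24 below 0, but in the second set alone the median was 0.05, with 15 of 24 above 0 (test direction up, adjusted p = 0.740). The lowest p-values belonged to SESN1, a stress-induced inhibitor of mTORC1 signalling, with -0.50 (SE 0.10), MDM2, the ubiquitin ligase of p53, with -0.41 (SE 0.12), GADD45A with -0.43 (SE 0.19) and ZMAT3 with -0.34 (SE 0.15). The value for GADD45A joins opposite signs, -0.93 (SE 0.13) in the first set and 0.34 (SE 0.13) in the second set. Antigen presentation genes had a median of 0.16, with 14 of 15 above 0. HLA-C (0.34, SE 0.11) and HLA-F (0.34, SE 0.17) encode class I molecules, NLRC5 (0.21, SE 0.09) their transactivator, and TAPBP (0.16, SE 0.07) the protein that joins them to the peptide transporter. Epithelial genes had a median of 0.15, with 12 of 13 above 0, among them ELF3 (0.32, SE 0.20), JUP (0.19, SE 0.09), KRT80 (0.16, SE 0.13) and PKP3 (0.14, SE 0.11). In the second set alone their median was -0.02, with 8 of 12 below 0 (test direction down, adjusted p = 0.720).

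By camera with the preset correlation, 5 of 32 lists were called over both sets: mitochondrially encoded genes (down, adjusted p = 3.14e-05), histones (down, adjusted p = 6.92e-05), antigen presentation (up, adjusted p = 0.00210), p53 targets (down, adjusted p = 0.0154) and epithelial genes (up, adjusted p = 0.0311). With an estimated correlation the adjusted p was 0.375, 0.577, 0.859, 0.875 and 0.875 in the same order, and fry called 0 lists. Adjusted over the list alone, 3 histone genes and 1 p53 target were lower, and 0 genes of the other called lists passed. Over all genes tested, 0 members of any list passed. The mitochondrial and histone lists were called in 10 of 10 fits that left out 1 library, antigen presentation in 8 (not without EV replicate 5 or OE replicate 4), p53 targets in 5 (not without EV replicates 1, 3 or 5 or OE replicates 2 or 4) and epithelial genes in 2 (without EV replicate 4 or OE replicate 5). The number of lists called was 9 without EV replicate 2, 8 without OE replicate 5, and 3 without EV replicate 1 or EV replicate 3. The GC and length offsets, chosen after the data were seen, ended the call of the epithelial list (median 0.15 to 0.09). The other 4 stayed called, but the median went from 0.16 to 0.10 for antigen presentation and from -0.13 to -0.08 for mitochondrially encoded genes, beside -0.08 to -0.09 for p53 targets and -0.40 to -0.38 for histones.

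**Figure D1:**
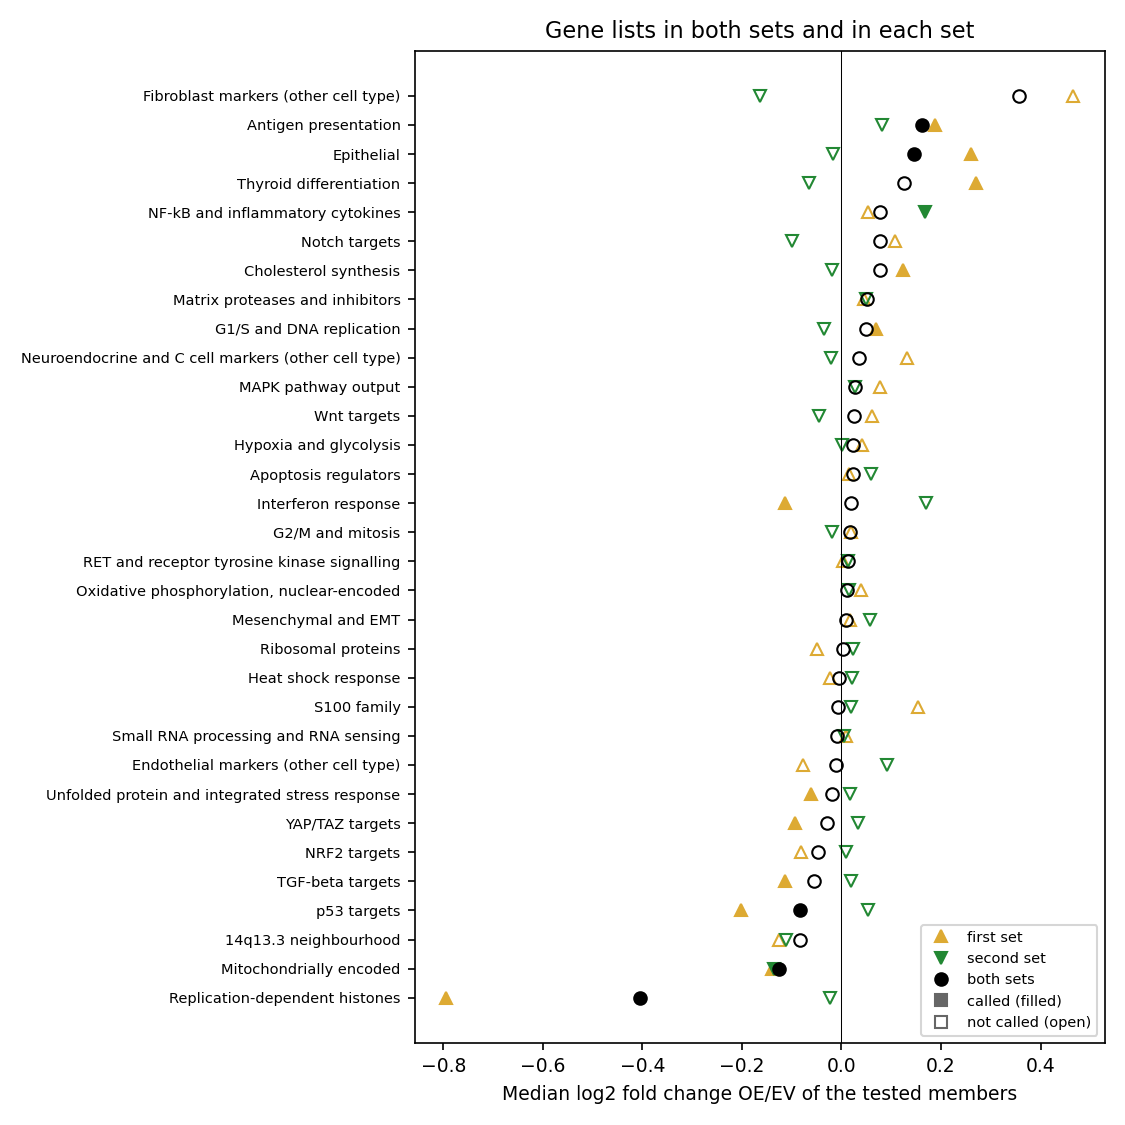
Median log2 fold change (OE over EV) of the tested members of each gene list, in both sets (circles), the first set (triangles pointing up) and the second set (triangles pointing down), filled where camera with the preset correlation called the list. The histone list has medians of -0.79 in the first set and -0.02 in the second set, and the mitochondrially encoded list -0.14 and -0.13.

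No single gene passed the edgeR test over both sets: of 14217 genes, 0 were higher and 0 lower, and 812 had an unadjusted p under 0.05 (452 higher, 360 lower, with 711 such genes given by chance). Limma-voom called 0 genes. DESeq2 called 6, named here after their values were seen: SAA1, an acute-phase protein (0.90, SE 0.19 in the edgeR fit), and DEDD2 (0.31, SE 0.07) were higher, and SESN1, the arrestin family member ARRDC3 (-0.59, SE 0.13), ANKRA2 (-0.60, SE 0.11) and AC005839.1 (-1.48, SE 0.28) were lower. The median SE was 0.11. The 95% interval of the change lay within 2-fold for 91.3% of the genes and within 1.5-fold for 75.7%. This bounds a change common to both sets, not the change in either set. In the fits of each set alone, the interval lay within 2-fold for 82.3% (first set) and 77.6% (second set). It lay within 1.5-fold for 62.4% and 61.7%.

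The remaining lists were not called over both sets. NF-kB targets and cytokines came closest, with a median of 0.08 (adjusted p = 0.0518), and among them SOD2 had 0.23 (SE 0.07) and the chemokine CXCL1 0.27 (SE 0.09). Medians were 0.12 for thyroid differentiation (adjusted p = 0.159), where the lineage factor PAX8 had 0.17 (SE 0.08) and the oxidase DUOX1 0.61 (SE 0.35), 0.05 for matrix proteases (adjusted p = 0.0924), where MMP15 had 0.40 (SE 0.12) and MMP14 0.14 (SE 0.06), and 0.05 for G1/S and DNA replication (adjusted p = 0.267). For signalling lists they were 0.03 for MAPK output (adjusted p = 0.615), 0.01 for RET and receptor tyrosine kinases (adjusted p = 0.618), where VEGFA had 0.24 (SE 0.11), 0.03 for Wnt (adjusted p = 0.759), 0.08 for Notch (adjusted p = 0.759), -0.03 for YAP/TAZ (adjusted p = 0.386), -0.05 for TGF-beta (adjusted p = 0.410) and -0.05 for NRF2 (adjusted p = 0.267). Stress and metabolic lists had medians of -0.02 for the unfolded protein and integrated stress response (adjusted p = 0.267), with SLC7A11, the cystine transporter, at -0.37 (SE 0.12), -0.0048 for heat shock (adjusted p = 0.681), 0.02 for hypoxia and glycolysis (adjusted p = 0.386), 0.08 for cholesterol synthesis (adjusted p = 0.278) and 0.01 for nuclear-encoded oxidative phosphorylation (adjusted p = 0.414). Apoptosis regulators had 0.02 (adjusted p = 0.618), G2/M and mitosis 0.02 (adjusted p = 0.681) and ribosomal proteins 0.0026 (adjusted p = 0.938, test direction down). Test and median differed in sign for interferon response (median 0.02, mean -0.02, adjusted p = 0.851), mesenchymal genes (median 0.01, mean -0.03, adjusted p = 0.759), the S100 family (median -0.01, mean 0.02, adjusted p = 0.681), small RNA processing (median -0.01, mean 0.03, adjusted p = 0.681) and endothelial markers (median -0.01, mean -0.05, test direction up, adjusted p = 0.681). Fibroblast markers (3 tested, median 0.36, adjusted p = 0.514) and neuroendocrine markers (3 tested, median 0.04, adjusted p = 0.681) gave no call, and 1 of 12 leukocyte markers was detected well enough to be tested.

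Several of these lists were called by camera when 1 library was left out of the fit over both sets. Without EV replicate 2, ribosomal proteins (median 0.12, adjusted p = 1.53e-05), nuclear-encoded oxidative phosphorylation (0.11, adjusted p = 2.25e-05), NF-kB targets and cytokines (0.12, adjusted p = 0.0114), the S100 family (0.16, adjusted p = 0.0253) and matrix proteases (0.10, adjusted p = 0.0415) were called up. The thyroid differentiation median became -0.0053. Interferon response was called down without EV replicate 5 (-0.19, adjusted p = 0.00482) or OE replicate 4 (-0.23, adjusted p = 1.21e-04) and up without OE replicate 5 (0.13, adjusted p = 0.0403). Cholesterol synthesis was called up without EV replicate 5 (0.14, adjusted p = 0.0105) or OE replicate 4 (0.16, adjusted p = 0.00118). NF-kB targets were also called up without OE replicates 1, 2, 3 or 5 (adjusted p = 0.0322, 0.0274, 0.0419 and 0.0394), matrix proteases without OE replicate 5 (0.11, adjusted p = 0.00554), and the PTCSC3 neighbourhood down without OE replicate 2 (-0.12, adjusted p = 0.0274). With an estimated correlation, run after the data were seen, 0 lists were called in any of the 10 fits that left out 1 library, the lowest adjusted p being 0.247. These calls therefore rest on the preset correlation, and also on which libraries remain. Relative to the mean over the 10 libraries, interferon medians were 0.63 and 0.94 in EV and OE replicate 4, and -0.40 and -0.35 in replicate 5. Leaving out 1 of these libraries makes the groups unequal in replicate number, which moves this list by itself. The same holds for cholesterol synthesis (-0.41 and -0.47, against -0.03 and -0.02). Ribosomal proteins were at 0.44 in EV replicate 2.

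In the first set alone, 5 genes fell in OE cells and 0 rose. ATF3 (ENSG00000162772, chromosome 1, 212565334 to 212620777), a stress-induced transcription factor, went from 31.2 ± 1.84 CPM in EV to 11.2 ± 1.39 in OE (SD, n = 3), a log2 change of -1.49 (SE 0.13, adjusted p = 0.0102). The nuclear long non-coding RNA NEAT1 (ENSG00000245532, chromosome 11, 65422774 to 65445540) went from 338 ± 7.69 to 194 ± 3.55 CPM, a change of -0.81 (SE 0.08, adjusted p = 0.0153). KLF10 (ENSG00000155090, chromosome 8, 102648779 to 102655902), an early TGF-beta response factor, fell from 155 ± 8.23 to 81.0 ± 7.89 CPM (-0.95, SE 0.10, adjusted p = 0.0198). TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600), which binds thioredoxin and restrains glucose uptake, fell from 121 ± 6.01 to 72.0 ± 2.40 CPM (-0.76, SE 0.09, adjusted p = 0.0332). NR1D1 (ENSG00000126368, chromosome 17, 40092787 to 40100725), a repressor of the circadian clock, fell from 45.8 ± 1.94 to 26.6 ± 1.73 CPM (-0.80, SE 0.10, adjusted p = 0.0469). Each of the 5 was lower in all 3 OE libraries than in any of the 3 EV libraries.

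**Figure D2:**
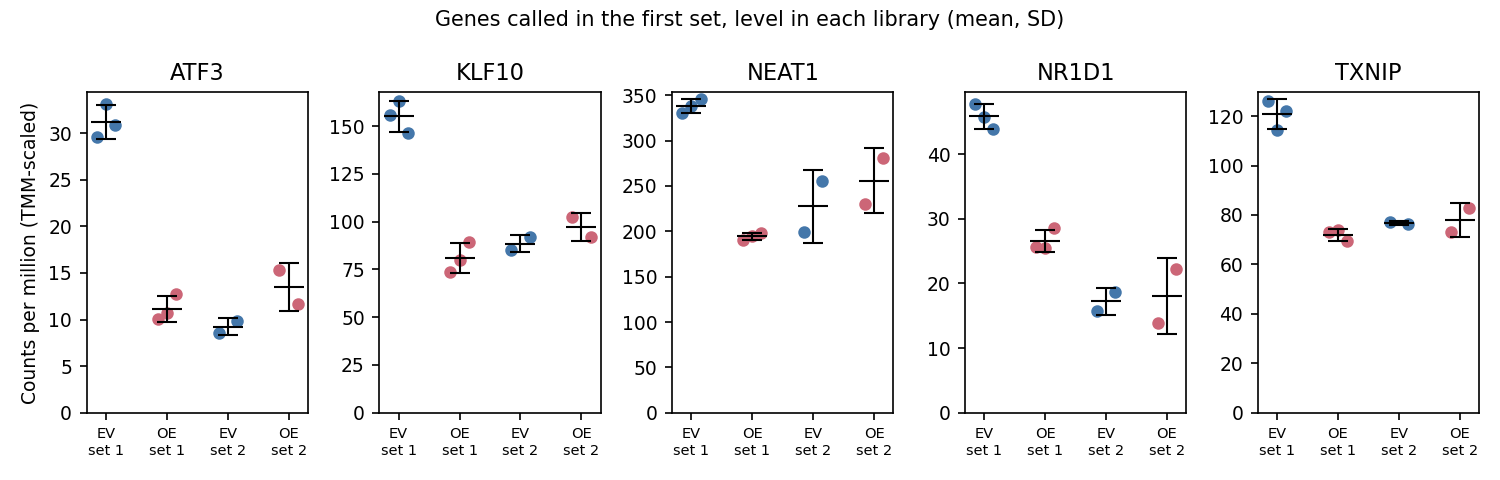
TMM-scaled CPM of the 5 genes called in the first set, 1 point per library, with the mean and SD of each group. ATF3 falls from 31.2 to 11.2 CPM in the first set and stands at 9.21 in EV and 13.5 in OE in the second set.

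Histone and p53 target lists were called lower in the first set, which is part of the fit over both sets. The 14 tested histone genes had a median of -0.79 (adjusted p = 4.33e-10 by camera, adjusted p = 0.0878 with an estimated correlation), and 8 were lower when adjusted over the list alone. Targets of p53 had a median of -0.20 (adjusted p = 3.02e-05, and 0.180 as adjusted p with an estimated correlation), with 6 lower when adjusted over the list alone, and MDM2 had -0.62 (SE 0.10), SESN1 -0.66 (SE 0.11) and GADD45A -0.93 (SE 0.13). Interferon response genes had a median of -0.11 (adjusted p = 0.00202, and 0.269 as adjusted p with an estimated correlation), with 3 lower and 1 higher when adjusted over the list alone. IFI6 had 0.59 (SE 0.14) and IRF9 -1.23 (SE 0.42). The mitochondrially encoded list (median -0.14, adjusted p = 0.00207) held 2 genes that were lower when adjusted over the list alone, and the unfolded protein and integrated stress response (median -0.06, adjusted p = 0.0191) 6 lower and 1 higher. Lists for TGF-beta (median -0.11, adjusted p = 0.0463) and YAP/TAZ targets (median -0.09, adjusted p = 0.0489) were also called down. Epithelial genes (0.26, adjusted p = 9.29e-05), antigen presentation (0.19, adjusted p = 0.00182), thyroid differentiation (0.27, adjusted p = 0.0356), cholesterol synthesis (0.12, adjusted p = 0.0386) and G1/S and DNA replication (0.07, adjusted p = 0.0407) were called up. In all, 12 of 32 lists were called (5 up, 7 down). With an estimated correlation 0 were, the adjusted p being 0.399, 0.326, 0.269 and 0.470 for the mitochondrial, stress, TGF-beta and YAP/TAZ lists and 0.148, 0.180, 0.415, 0.269 and 0.415 for the lists called up. Fry called 11 lists, 9 of these 12 and not thyroid differentiation, G1/S or YAP/TAZ targets, and with matrix proteases (adjusted p = 0.0358 by fry) and fibroblast markers (3 tested, median 0.47, adjusted p = 0.0231 by fry) in addition. The collagen gene COL1A1 had 0.76 (SE 0.22) and was the 1 fibroblast marker higher when adjusted over the list alone. Without EV replicate 2 the calls of thyroid differentiation (median 0.09, adjusted p = 0.320), TGF-beta targets (-0.12, adjusted p = 0.0798) and the stress response list (-0.05, adjusted p = 0.236) ended. The thyroid members were at a median of -0.52 in EV replicate 2, relative to their mean over the 10 libraries, against -0.10 in EV replicate 1 and 0.05 in EV replicate 3.

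Shares of counts and GC trends of the libraries moved with the groups in this set. Whether they reflect library quality or the cells was not tested. Mitochondrial ribosomal RNA made up 0.679% ± 0.0491 of counts in EV and 0.519% ± 0.00746 in OE (SD, n = 3). All mitochondrial counts took 4.94% ± 0.238 in EV and 4.39% ± 0.106 in OE. In the second set they took 4.63% ± 0.254 and 4.17% ± 0.0995 (SD, n = 2). The deviation of a library from the others of its set correlated with GC content across genes at r = -0.24 to -0.08 in the 3 EV libraries and 0.05 to 0.34 in the 3 OE libraries. Genes are not independent replicates in such a correlation.

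Of 14340 genes tested in the first set by edgeR, 1268 had an unadjusted p under 0.05. DESeq2 called 76 genes (24 higher, 52 lower), and limma-voom 4 of the 5 named (not NR1D1). The count of 5 rests on which libraries are used. It was 0 without EV replicate 1, 0 without OE replicate 1, 0 without OE replicate 2, 1 without EV replicate 3, 1 without OE replicate 3, and 1578 without EV replicate 2.

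Without EV replicate 2, the library that stood apart, the first set compares 2 EV with 3 OE libraries. It then gave 896 genes higher and 682 lower in OE, the 5 genes above among them. The following were named after their values were seen. MDM2 (log2 change -0.70, SE 0.07), GADD45A (-0.79, SE 0.07), BTG2 (-0.76, SE 0.09), ZMAT3 (-0.64, SE 0.08) and the nuclear RNA MALAT1 (-0.96, SE 0.10) were lower. Complement C3 (0.68, SE 0.08), the interferon-induced IFI6 (0.75, SE 0.08), the aldose reductase AKR1B1 (0.53, SE 0.06) and the secretory kinase FAM20C (0.55, SE 0.06) were higher. Camera called 13 lists (8 up, 5 down), among them ribosomal proteins (0.16, adjusted p = 6.63e-05, with 11 of 32 genes higher over all genes tested) and nuclear-encoded oxidative phosphorylation (0.16, adjusted p = 4.63e-05, with 8 of 30 higher). With an estimated correlation 0 lists were called, the lowest adjusted p being 0.309. With EV replicate 2 kept, ribosomal proteins had a median of -0.05 and nuclear-encoded oxidative phosphorylation 0.04, and neither was called (adjusted p = 0.677 and 0.516). Deviations correlated with transcript length at r = 0.21 and 0.25 in the remaining EV libraries and at -0.11, 0.02 and 0.13 in the OE libraries. With GC and length offsets, a test chosen after the data were seen, both lists stayed called without EV replicate 2, at 0.13 (adjusted p = 2.03e-04, and adjusted p = 0.742 with an estimated correlation) and 0.21 (adjusted p = 4.58e-07, and adjusted p = 0.498 with an estimated correlation). This fit is 1 of 6 that left out a library of the set, and the other 5 gave 0 or 1 gene.

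In the second set, with 2 libraries per group, no gene passed the unpaired test. With the replicate number as a block, 71 genes were called (47 higher, 24 lower), but that fit has 1 residual degree of freedom. Of the 5 genes called in the first set, ATF3 had 0.55 (SE 0.20), going from 9.21 ± 0.913 CPM in EV to 13.5 ± 2.59 in OE (SD, n = 2), while NEAT1 had 0.16 (SE 0.14), KLF10 0.13 (SE 0.09), NR1D1 0.06 (SE 0.23) and TXNIP 0.01 (SE 0.10). Mitochondrially encoded genes were again called down as a list (median -0.13, 14 of 15 below 0, adjusted p = 0.0184), with MT-ND2 at -0.19 (SE 0.07). NF-kB targets and cytokines were called up (median 0.17, 20 of 24 above 0, adjusted p = 0.0184), with NFKBIA, the inhibitor that NF-kB itself induces, at 0.28 (SE 0.10) and CXCL1 at 0.23 (SE 0.16). With an estimated correlation the adjusted p was 0.991 for each, and fry called 0 lists. The histone list had a median of -0.02 (test direction up, adjusted p = 0.917) and interferon response 0.17 (adjusted p = 0.610). By edgeR 0 of 14419 genes were called, and 158 had an unadjusted p under 0.05, where chance gives 721. Libraries of this set were more alike by replicate number (r = 0.990 for EV and OE replicate 4 and for EV and OE replicate 5) than by group (0.986 for the EV and for the OE libraries), so the spread within a group holds that difference too and a count of 0 says little. Limma-voom called 0 genes and DESeq2 1, AC004556.1 (0.74, SE 0.11 by edgeR), named after its value was seen.

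**Figure D3:**
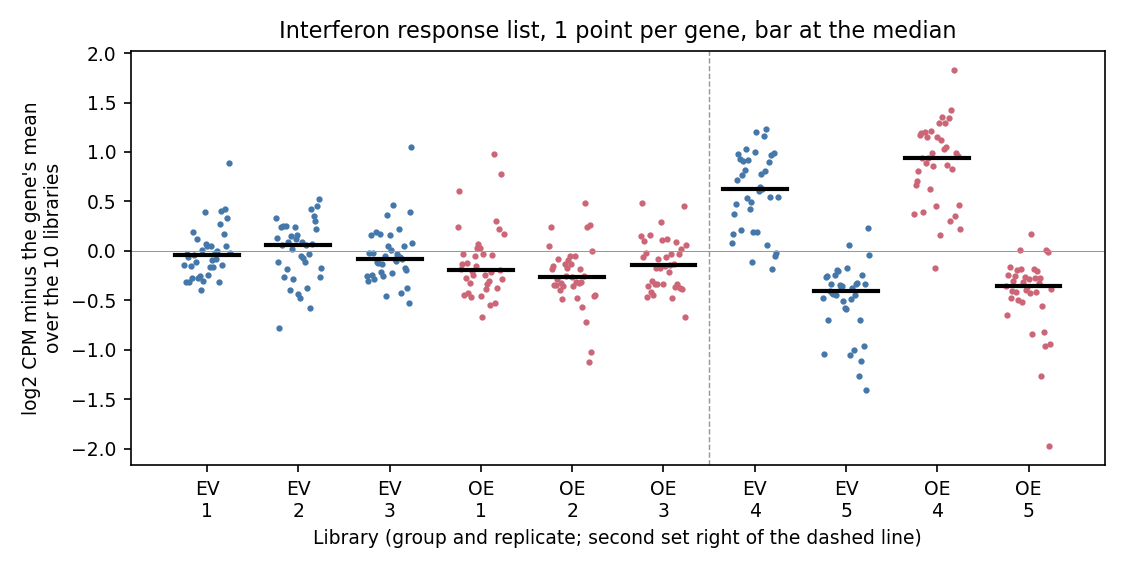
Log2 CPM of each interferon response gene minus its mean over the 10 libraries, 1 point per gene, with a bar at the median of the library. The median is 0.63 in EV replicate 4 and 0.94 in OE replicate 4, and -0.40 in EV replicate 5 and -0.35 in OE replicate 5.

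The test of the difference between the sets called ATF3, whose change was higher in the second set by 2.03 (SE 0.23, adjusted p = 0.0146, edgeR). KLF10 differed by 1.06 (SE 0.15, adjusted p = 0.0826), NEAT1 by 0.96 (SE 0.17, adjusted p = 0.211), TXNIP by 0.76 (SE 0.14, adjusted p = 0.235) and NR1D1 by 0.85 (SE 0.24), which did not pass. Of 14217 genes, 1 was called and 496 had an unadjusted p under 0.05. Limma-voom called 1 gene and DESeq2 9, all with a higher change in the second set. The call of ATF3 ended without EV replicate 4, EV replicate 5, OE replicate 1, OE replicate 2 or OE replicate 4 (adjusted p = 0.249, 0.103, 0.0797, 0.112 and 0.119). Without EV replicate 2, 7 genes were called.

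Log2 changes of the sets, which share no libraries, correlated across 13947 genes at r = 0.0088 (Spearman rho 0.05). None of the 5 genes called in the first set had the same sign in the second set (0 of 5). An unadjusted p under 0.05 in each set was found for 20 genes, of which 10 had the same sign, where independent lists of that size would share 12.

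**Figure D4:**
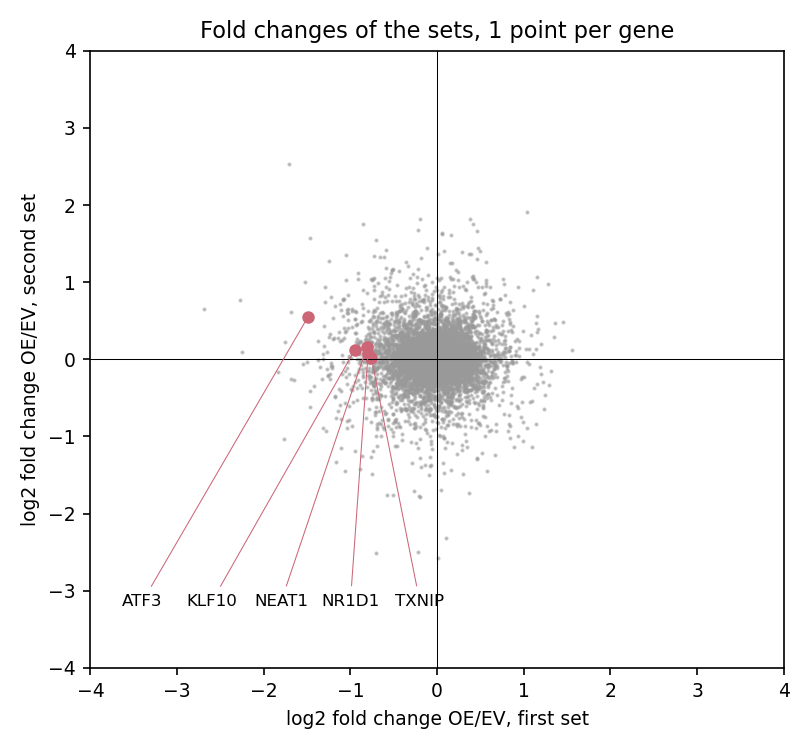
Log2 fold change (OE over EV) of each of 13947 genes in the first set (horizontal) and the second set (vertical), with the 5 genes called in the first set in red. The cloud has r = 0.0088, the 5 genes lie between -1.49 and -0.76 on the horizontal axis and between 0.01 and 0.55 on the vertical axis, and 1 gene lies beyond the axes.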

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

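The search for libraries far from the others of their group was planned, and so were the splits of libraries for the counts over both sets and in the first set, though what the split for genes over both sets would show was written down after that count was known. Chosen only after the results were seen were the tests on the 5 genes of the first set, on the count without EV replicate 2, and on the histone and mitochondrial lists, with MALAT1 added last to the list of nuclear-retained RNAs.

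In 174 tests, the level of a named gene or a share of counts in 1 library lay far from the other 4 of its group in 10 cases, where chance gives 8.7. OE replicate 4 held 4 of them: the chemokine CXCL1 at 168 CPM (others 121 to 127), S100A2 at 290.4 (150 to 189), the Wnt inhibitor DKK1 at 8.39 (from 4.49) and MDM2 at 109 (148 to 160). EV replicate 2 held 3: the kinetochore gene NUF2 at 72.8 CPM (55.1 to 59.9), the Notch target HEY1 at 7.75 (2.67 to 3.72), and processed pseudogenes, which took 0.595% of its counts (0.421% to 0.461%). EV replicate 4 held 2, the junction gene JUP at 41.3 CPM (28.7 to 32.3) and the epithelial factor ELF3 at 7.26 (3.33 to 4.39). OE replicate 2 held 1, the histone gene HIST1H4H at 2.44 CPM (others from 0.774).

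The 5 genes lower in OE in the first set (median -0.81), with ATF3 differing between the sets by 2.03, were weighed first. Without EV replicate 2 their median was -0.80 (SE 0.08), so the fall was present in the remaining libraries too. The test that called the 5 genes favours levels that agree within a group, as theirs did among these EV libraries. Leaving out EV replicate 2 could therefore hardly change the median, and this decides nothing about that library as a cause. With each library's GC and length trend removed the median was -0.90 (SE 0.09), so these trends cannot account for all of the pattern. The trend removal ended the call of NEAT1, whose change went from -0.81 (SE 0.08) to -0.75 (SE 0.15), mainly through the wider SE. A general immediate-early response in EV cells would lower its other genes too, but 22 of them had a median of 0.0529 (SE 0.11). They went both ways, with KLF4 at -0.35 (SE 0.10), SGK1 at -0.39 (SE 0.13), FOSB at 0.35 (SE 0.11) and JUNB at 0.28 (SE 0.11). They did not fall as a group, but a response of some of them stays open. The median of 12 other nuclear-retained RNAs was -0.10 (SE 0.10), with PVT1 at -0.60 and FTX at -0.48 among them. That list left out MALAT1, which had -0.91 (SE 0.16). With it the median of 13 was -0.10 (SE 0.12), but 1 added gene can hardly move such a median. Without MALAT1 the listed RNAs ranged from -0.60 (PVT1) to 0.09 (NORAD). They did not fall as a group as NEAT1 did. With such a spread this does not exclude more nuclear RNA in EV libraries, and a part played by it in NEAT1 stays open. A response to the vector that was present in 1 set, or a difference in culture between EV and OE cells of that set, may underlie the pattern and cannot be told apart here, and other splits of the 6 libraries gave at most 0 genes against 5, but 10 splits are too few for a share under 0.05 (1 of 10).

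The count without EV replicate 2 (1578 genes) was weighed next. With the GC and length trends removed as well, 966 genes were called (646 higher, 320 lower), 603 of them among the 1578, so these trends do not account for all of the count. Of the 1561 genes also tested in the second set, 954 (61.1%) had the same sign there. Splits of those 4 libraries that grouped EV replicate 4 with OE replicate 4 or with OE replicate 5 gave 55.0% and 52.3%. Such splits are too few to judge that share. The highest count of any other split of the 5 libraries was 1 (1 of 10 splits as large), and 10 splits are too few for a share under 0.05. A difference between cultures that follows the groups within the first set may produce such a count as well as the transcript could, and the design does not separate them.

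Lower histone and mitochondrial ribosomal RNA in OE libraries of the first set was weighed last. A candidate explanation is that the EV libraries took up more RNA without a poly(A) tail, since most of these transcripts lack one or carry short ones. Of 23 other RNAs of this kind only 2 were tested, RN7SL2 (0.05, SE 0.55) and SNORA73B (-0.29, SE 0.32), with a median of -0.12, so the test decides nothing and the explanation stays open. Because histone RNA also follows DNA replication, a lower share of OE cells in S phase is another candidate, not tested beyond the G1/S list. Fewer such cells would lower that list, but its median was 0.07 in that set, with 22 of 30 tested genes above 0. Camera with the preset correlation called it up (adjusted p = 0.0407). These values go against this explanation but do not exclude it, since the call did not hold with an estimated correlation (adjusted p = 0.415).

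Regrouping the libraries within the sets gave 60 splits, the real one included. For the count of genes over both sets (0, with 8 the highest other) the splits decide nothing, since any of the 60 is as large as 0. Chance could not be excluded for genes at an unadjusted p under 0.05 (812, with 18 as large and 2234 the highest other), for the difference between sets (1, with 22 as large and 141 the highest other), for lists called (5, with 33 as large and 14 the highest other), or for the correlation of the sets (0.0088, with 26 as large and 0.0606 the highest other). Nor could it be for the size of the median change of the mitochondrially encoded list (0.125, with 3 as large and 0.129 the highest other) and the histone list (0.404, with 6 as large and 0.561 the highest other). These splits decide little for either list. All that were as large for histones kept the real groups of the first set, where that change arose. The others as large for the mitochondrial list kept the real groups but for 1 EV and 1 OE library, which changed places. The highest counts for the difference between sets came from splits that set replicate 4 against replicate 5 of the second set, which shows a structure of those libraries. For the 12 lists of the first set, 1 of 10 splits was as large and the highest other gave 6, with too few splits for a share under 0.05.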

How the results depend on the processing

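The edgeR version 4 test, camera with a variance trend and the GC and length offsets were chosen after the data were seen; the other alternatives were planned. Genes called over both sets stayed at 0 in all 10 fits without 1 library and under every other setting except the DESeq2 test (6) and no filter on low counts (23). In the first set (5) the count was 76 with the DESeq2 test, 90 without a filter, 8 with a spread pooled over both sets, 1 at a fold change of at least 2, 15 with the GC and length offsets (1 higher, 14 lower, 4 of the 5 kept), 966 with these offsets and EV replicate 2 left out, and 0 to 1578 without 1 library. In the second set (0) it was 1 with the DESeq2 test, 12 without a filter and 0 to 1 without 1 library, the 1 being BOLA2B without EV replicate 5. There the lone EV or OE library is assumed to vary like the other group. The difference between sets (1) called 9 genes with the DESeq2 test, 28 without a filter, 3 with the offsets and 0 to 7 without 1 library. Without a filter, genes with counts in few libraries enter, and in the second set these included BOLA2B, SMIM11A and pseudogenes. Gene lists called over both sets (5) were 0 with an estimated correlation, 0 with fry, 3 with no set term, 12 in the first set alone, 2 in the second set alone, 7 with the offsets (4 shared), 6 with a variance trend (NF-kB added), and 3 to 9 without 1 library. The fold changes of the sets compared had r = -0.0207 (without EV replicate 5) to 0.0437 (without OE replicate 5). Where no reason is given, the cause was not tested.

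Among the named genes, 1613 of the values under alternatives kept direction and side of the threshold, 37 fell short of it, 6 passed it and 6 changed sign. These were values without 1 library for FOXA1 (-0.12 to 0.0492), RALGAPA1 (-0.21 to 0.0510) and the small log2 fold change of NCAM1, both sets (-0.0604 to 0.0937). No alternative could be run for the overexpressed transcript, which was not among the gene names and so was not measured.

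The replicate numbers were checked for pairing. Deviations of EV and OE libraries of one number correlated across genes at -0.11, 0.0035, 0.16, 0.31 and 0.31 for replicates 1 to 5. The values for 4 and 5 are equal by construction, with 2 libraries per group. With 2 of 5 not over 0.1, the numbers were not taken as pairs, although the design text speaks of 5 pairs. Both low values belong to the first set, so this choice has little ground in the second set. There libraries were more alike by number (r = 0.990) than by group (0.986), and the unpaired test is weak. With the replicate number as a block, genes called were 0 over both sets, 1 in the first set and 3 for the difference between sets, and 6 lists were called. In the second set 71 genes were called (47 higher, 24 lower, with 1 residual degree of freedom). Named after their values were seen, HMOX1, IFI6, ISG15, OAS1, IRF7 and the ribosomal protein gene RPS29 were among those higher. MT-ATP6 and MT-ND4 were among those lower. A comparison chosen after the data were seen set the first set without EV replicate 2 against the second set under the block. It had 25 genes called in both, whatever their sign, where lists drawn evenly from all genes would share 7.85. Genes with high counts pass more readily in both fits, so an excess can arise without a shared change. Of the 71 genes, 46 (64.8%) had the same sign in the first set, with r = 0.0350 over all genes. Depth limits what rests on few counts: the floor of 3 counts is 0.166 to 0.190 CPM per library.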

Other observations

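The comparisons here, of sets, of replicate numbers and of single libraries, were chosen after the data were seen, except the reading of the authors' own comparisons. The sums over near-identical copies were also taken after those were seen. Genes named here outside the fixed rule were chosen after their values were seen.

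In the second set, expression differed by replicate number in EV and OE cells. Interferon response genes fell from replicate 4 to replicate 5 in EV and OE cells alike (median -1.26), with 33 of 38 tested members lower over all genes tested. IFIT3 fell by 1.49 (SE 0.07), ISG15 by 1.55 (SE 0.10) and OAS2 by 1.83 (SE 0.15). Antigen presentation genes fell as well (9 of 15, median -0.33). Targets of p53 rose (15 of 24, median 0.46), with the cell cycle inhibitor CDKN1A up by 0.79 (SE 0.05), and so did cholesterol synthesis genes (16 of 22, median 0.43), with INSIG1 up by 0.76 (SE 0.07). The immediate-early gene EGR1 (2.16, SE 0.20) rose too. In all 624 genes were higher and 641 lower in replicate 5, and camera called 10 lists, 0 with an estimated correlation (adjusted p = 0.419 for the interferon, p53 and cholesterol lists and 0.457 for antigen presentation). This fit had no group term, so the EV and the OE library of each number stood as its replicates. What a replicate number stands for is not known.

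Sets differed more than groups did. With the group as a term, 1318 genes were higher and 1303 lower in the second set than in the first set. Histones fell (9 of 13, median -1.50), as did heat shock genes (9 of 13, median -0.46) and cholesterol synthesis genes (12 of 22, median -0.35), while G1/S and DNA replication genes rose (18 of 30, median 0.25). EGR1 fell by 3.41 (SE 0.36) and the MAPK phosphatase DUSP6 by 1.12 (SE 0.10). Camera called 10 lists, and 0 with an estimated correlation (adjusted p = 0.284 for histones, heat shock and G1/S and 0.387 for cholesterol synthesis). A level of EV cells in 1 set is therefore no reference for OE cells of the other.

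The authors' comparisons of 1 OE with 1 EV library listed 4 genes at an adjusted p under 0.05 for replicate 4 (2 higher, 2 lower, of 21397) and 6 for replicate 5 (3 higher, 3 lower, of 21288), with 0 shared. They compare libraries, not conditions. Most of the genes are pseudogenes or near-identical copies, and counts of BOLA2B, for example, were 400 in EV replicate 2, 314 in EV replicate 4 and 2 to 23 in the other libraries. Reads moved between copies would leave the sum of both copies level, but the sum of BOLA2B and BOLA2 differed by -4.74 (log2) in replicate 4. For SMIM11A and SMIM11B in replicate 5 it differed by 3.96, but SMIM11B had 0 counts in both libraries, so this sum is SMIM11A alone. U2AF1L5 in replicate 5 went from 957 to 111 counts while its copy U2AF1 went from 67 to 186, and their sum differed by -1.91 against -3.22 for U2AF1L5 alone, so moved reads stay open as a part of that difference. Loss of reads that match both copies was not tested.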
